A study of Homo sapiens with 8 samples.

How the data were processed

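Polyadenylated RNA was measured by RNA sequencing in 8 libraries from human cell lines. HEK293T, a line derived from embryonic kidney, was treated with sodium arsenite, an oxidative stressor, and carried a control siRNA or an siRNA against eIF2A. H9, a human embryonic stem cell line, carried a control shRNA or an shRNA against eIF2A. The labels place 2 libraries in each of the 4 groups and number them as sets without saying what a set is. They do not say that the libraries of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical. Ribosome profiling named in the series' design is not analysed here.

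Per the labels' protocols, RNA was extracted with TRIzol and libraries were made with the TruSeq Stranded mRNA kit. Reads were processed with cutadapt and STAR 2.5.2b against hg19, per the submitters' processing notes. The deposited values are raw counts per RefSeq transcript accession, with no normalization, as their whole numbers and unequal totals show. The counting program, its strand setting and the annotation version are not given in the sources used here, so a gene and an overlapping antisense partner may share counts. Each file listed 19305 accessions and 5 special counters of the kind that HTSeq writes, which were kept out of library sizes and tests. Reads assigned to no counted feature made up 14.95 to 20.84% of all reads listed, and reads aligned to more than 1 place made up 4.11 to 4.54%. The settings of the count are not given, so reads without a feature need not lie outside genes and may include intronic reads. Because these multiply aligned reads were set aside, genes with near-identical copies, such as HSPA1A and HSPA1B or ribosomal protein genes with pseudogenes, are less certain than others. Gene symbols for 18888 accessions came from a RefSeq gene table and for 223 from GENCODE tables, and the 194 accessions left without a name held at most 0.03% of a library's gene counts. No genomic coordinates are given, because the reference at hand was of another build than hg19.

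Gene counts per library ranged from 21837052 to 32318668. No duplicate libraries were found: the chi-square per degree of freedom between the replicates of a group, over genes with at least 20 counts, was 4.91 for the HEK293T controls and 1.35 to 1.80 for the other groups, where 1 is sampling noise alone.

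Counts were tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr, libraries were scaled with TMM, and 4 group means were fitted to all 8 libraries, which leaves 4 residual degrees of freedom. Each gene's spread is thus shared by both lines, although the HEK293T controls differed more between replicates than the other groups. The quasi-likelihood F test (robust, two-sided) gave each p-value, adjusted by the Benjamini-Hochberg method over all genes tested. A gene was called at an adjusted p under 0.05, and called genes with a change of at least 2-fold were counted too. The contrasts were eIF2A knockdown minus control in each line and the difference of these contrasts, H9 minus HEK293T. Log2 fold changes are given ± their standard error (SE), taken from the F statistic. Levels are given as CPM, counts scaled to a common library size with the TMM factors.

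A total of 24 gene lists were tested with camera in limma 3.58.1, with a preset correlation between genes of 0.01 and adjustment over the lists of a comparison; camera with an estimated correlation and fry were run beside it. Overlap of calls was tested with Fisher's exact test, two-sided, and compared with the overlap of independent lists. Named genes were chosen by a rule. EIF2A came first. For each line, the 10 called genes with the largest rise and the 10 with the largest fall were taken among genes with a mean of at least 1 CPM whose knockdown libraries lay on the same side of both controls. From each list that passed camera or held at least 3 called genes, up to 4 members with the smallest p were taken. For the difference between the lines, the 5 largest differences in each direction were taken, and for the overlap the 5 genes with the largest smaller change in the same and in opposite directions. POU5F1, NANOG and SOX2 in H9, ATF4, DDIT3, HMOX1 and HSPA1A in HEK293T, and NCBP1, NCBP2, EIF4E and EIF2S1 in both were taken whatever their test gave. The groups, tests, lists, this rule and the alternatives were fixed before the data were examined. The rule took more genes than the text could hold, so after the data had been seen the text was limited to at most 4 members of a list that passed camera and at most 2 of another list. Some genes that the rule took are not reported here.

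The alternatives were DESeq2's median-of-ratios size factors, upper-quartile scaling, no filter, a filter of at least 5 CPM in at least 2 libraries, DESeq2 1.42.0, limma-voom, only the 4 libraries of a line, the set number as a block, each library left out in turn, and an adjusted p under 0.01. With 1 library left out, the lone library of its group is assumed to vary like the others.

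After the data had been seen, a fit was added with each library's trend with GC content and transcript length removed. The trend was a natural spline with 5 degrees of freedom for each property, measured relative to the mean of the library's cell line and entered as an offset. Lengths and GC contents came from GENCODE transcripts matched by accession for 18545 genes and by symbol for 521, and 239 had none. Where several transcripts matched, the longest was used, so the corrected value of a single gene is less certain than that of a list. Upper-quartile scaling of the lists and named genes was also added after the data had been seen.

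The test was checked on simulated data made from the means, depths and spread of these libraries, with 200 genes changed per comparison in each of 3 simulations. Among 14358 genes tested, changes of 1 on the log2 scale were recovered in 87.5% of cases for H9 and 81.5% for HEK293T. For changes of 0.5 these shares were 65.1% and 70.2%. False calls made up 5.1% of calls for H9 and 5.5% for HEK293T. These counts were drawn from the kind of model that the test assumes, so a false share near that level was largely built in. Each gene had the same spread in all groups, so the wider spread of the HEK293T controls was not covered. Far fewer genes were changed than were called in the data, so the recovered shares need not hold there. With only a GC trend simulated for H9 over 14368 genes, the uncorrected fit called 9068 genes and the corrected fit called 2. The simulated trend was linear, had no part from length and used the same GC contents that the fit then removed. It checks that the fit works as written and does not show that the H9 calls left after it are free of bias. Figures were drawn with matplotlib 3.10.9.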

Results

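Transcript levels were measured in 8 RNA-seq libraries, 2 in each of 4 groups, to see what changes when eIF2A, an initiation factor that can bring initiator tRNA to the ribosome, is depleted in HEK293T cells under sodium arsenite and in H9 human embryonic stem cells. The series concerns the nuclear cap-binding complex and protein synthesis that resists stress. HEK293T control libraries held 22844053 and 32318668 gene counts and the eIF2A siRNA libraries held 29386824 and 28887591. H9 control libraries held 23043164 and 21945814 and the eIF2A shRNA libraries held 23848357 and 21837052. A total of 14565 genes were tested.

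The targeted transcript was lower in each knockdown library than in each control library of its line. EIF2A stood at 17.47 and 18.32 CPM in the HEK293T controls and at 5.58 and 5.98 CPM with siRNA. In H9 it stood at 15.81 and 14.76 CPM in the controls and at 5.03 and 4.67 CPM with shRNA. The log2 fold change of EIF2A was -1.63 ± 0.095 (SE) in HEK293T, which leaves 32.2% of the control level, and -1.66 ± 0.11 in H9, which leaves 31.7% (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 6.6e-15 and 2.3e-15). The depth of the knockdown did not differ detectably between the lines as measured (adjusted p of the difference = 0.94), but this depended on the fit: with the GC and length trend described below removed, the log2 fold change was -1.685 in HEK293T and -2.305 in H9 (adjusted p of the difference = 8.4e-04).

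**Figure D1:**
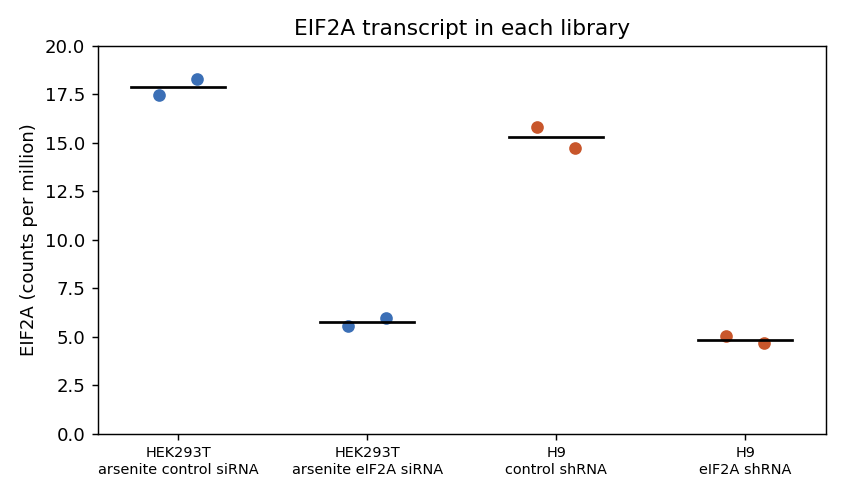
EIF2A in CPM (depth-scaled counts) in each of the 8 libraries, by group; points are libraries and black lines are group means of 2 libraries. The knockdown libraries lie between 4.67 and 5.98 CPM and the control libraries between 14.76 and 18.32 CPM.

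To assess what eIF2A depletion changes in arsenite-treated HEK293T cells, eIF2A siRNA was compared with control siRNA. By camera at its preset correlation, cholesterol synthesis transcripts and genes of the unfolded protein response of the endoplasmic reticulum fell and antioxidant genes rose slightly. None of these lists passed with the correlation estimated (adjusted p = 0.075, 0.53 and 0.28 with an estimated correlation), and the antioxidant genes did not pass with the GC and length trend removed (adjusted p = 0.051). Reads assigned to no counted feature also followed the groups, at 15.59 and 17.68% in the controls against 14.98 and 14.95% with siRNA. The 2 controls differed from each other more than other replicates (chi-square per degree of freedom 4.91). The list changes were not separated from such differences between libraries. The heme oxygenase transcript HMOX1 rose by 0.67 ± 0.037 on the log2 scale, from 124 to 196 CPM. Changes were small: of 4182 genes called, 2048 rose and 2134 fell, 2149 of them by less than 1.2-fold, and 98 changed at least 2-fold (51 higher, 47 lower). DESeq2 called 2742 genes, 22 of them at least 2-fold, and gave no adjusted p to 3389 of the 14565.

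In the cholesterol list, 14 of 22 genes fell and 2 rose, with a median log2 fold change of -0.22 (camera adjusted p = 1.8e-07; adjusted p = 0.075 with an estimated correlation). The sterol sensor partner INSIG1 fell by 0.45 ± 0.038 on the log2 scale, mevalonate decarboxylase MVD by 0.39 ± 0.042 and lanosterol synthase LSS by 0.33 ± 0.036. Of 20 genes of the unfolded protein response of the endoplasmic reticulum, 10 fell and 1 rose, with a median of -0.15 (camera adjusted p = 0.0011; adjusted p = 0.53 with an estimated correlation). HYOU1 had a log2 fold change of -0.38 ± 0.030, HSP90B1 of -0.32 ± 0.041, CRELD2 of -0.29 ± 0.039 and HERPUD1 of -0.28 ± 0.041.

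Of 24 NRF2 and antioxidant genes, 10 rose and 3 fell, with a median of 0.12 (camera adjusted p = 0.0075; adjusted p = 0.28 with an estimated correlation, and 0.051 with the GC and length trend removed). Without HEK293T arsenite eIF2A siRNA replicate 1 this median was 0.06. SQSTM1, an autophagy receptor, rose by 0.26 ± 0.032 and the ferritin light chain FTL by 0.24 ± 0.031, whereas PGD of the pentose phosphate pathway fell by 0.26 ± 0.032. Of 75 cytosolic ribosomal protein genes, 25 rose and 4 fell, with a median of 0.02 (camera adjusted p = 5.7e-04; adjusted p = 0.79 with an estimated correlation). RPL31 rose by 0.59 ± 0.032 and RPS12 by 0.48 ± 0.030. The median of this list was 0.08 without HEK293T arsenite control siRNA replicate 2, and the list no longer passed without HEK293T arsenite control siRNA replicate 1 (adjusted p = 0.37) or with the GC and length trend removed (adjusted p = 0.86). Adjusted over the list alone, 15 cholesterol genes, 10 unfolded protein response genes, 3 NRF2 genes and 5 ribosomal protein genes fell, and 2, 1, 10 and 25 rose.

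The other lists did not pass camera in HEK293T. In the integrated stress response list, 10 of 30 genes rose and 7 fell; SHMT2 of mitochondrial folate metabolism fell by 0.35 ± 0.030 and MTHFD2 of the same pathway rose by 0.40 ± 0.036. ATF4, the transcription factor of that response, had a log2 fold change of -0.04 ± 0.030 (adjusted p = 0.39), and DDIT3 had one of 0.14 ± 0.070 (adjusted p = 0.14). In the heat shock list, 6 of 23 genes rose and 8 fell, among them DNAJB1 (-0.34 ± 0.031) and BAG3 (-0.35 ± 0.038). HSPA1A was not measurable, with at most 1 count in a HEK293T library. Among immediate early genes, 3 of 20 rose and 7 fell: CCN1 rose by 0.59 ± 0.040 and JUN fell by 0.32 ± 0.030. Among p53 targets, 8 of 20 rose and 3 fell, with FDXR at -0.45 ± 0.050, MDM2, the ubiquitin ligase of p53, at -0.53 ± 0.062 and CDKN1A at 0.42 ± 0.066. Of the aminoacyl-tRNA synthetases, 7 of 19 rose and 3 fell. Among cap-binding and initiation factors, 14 of 53 rose and 10 fell, with EIF2D at -0.34 ± 0.037 and EIF4B at 0.26 ± 0.036. NCBP1, the large subunit of the nuclear cap-binding complex, rose by 0.21 ± 0.068 (adjusted p = 0.019) and EIF2S1 by 0.17 ± 0.056 (adjusted p = 0.024), and each lost its call when any of 3 of the 4 HEK293T libraries was left out. NCBP2 (0.08 ± 0.063, adjusted p = 0.40) and the cap-binding factor EIF4E (0.16 ± 0.073, adjusted p = 0.099) were not called.

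Counts in the remaining HEK293T lists went both ways or were few. Of nonsense-mediated decay factors, 6 of 16 rose and 1 fell, with RBM8A at 0.34 ± 0.039, and of known substrates of that decay 3 of 15 rose and 2 fell. DNA replication genes gave 9 of 24 higher and 4 lower, mitosis genes 8 of 24 higher and 4 lower, respiratory chain subunits 10 of 33 higher and 6 lower, and glycolysis and hypoxia genes 3 of 24 higher and 5 lower, with VEGFA at -0.56 ± 0.047. One member or none was called in either direction among the metallothionein, interferon, neural, trophoblast, fibroblast and histone lists. Pluripotency genes gave 2 of 28 higher and 4 lower, and mesoderm and endoderm markers 1 of 16 higher and 3 lower. The genes with the largest changes, taken among those with a mean of at least 1 CPM, were mostly of low abundance. CARMIL2, a regulator of actin capping, rose from 19.99 to 44.99 CPM (log2 fold change 1.16 ± 0.060), and the stress-induced genes NUPR1 and GDF15 rose by 1.197 ± 0.18 and 1.10 ± 0.21. The others that rose were SLC49A3, GNG13, C1orf116, AJM1, ANKRD1, GP1BA and ZNF470, by 1.04 to 1.80. Among these, the largest falls after EIF2A were in SLC43A3 (-1.36 ± 0.23) and the DNA repair gene BRCA2 (-1.32 ± 0.22, from 2.60 to 1.045 CPM), followed by GCM1, EPHA3, DNAJB13, TTC24, ARHGAP25, ITIH5 and TEX15. ANKRD1, ZNF470, GCM1, TTC24, ARHGAP25 and TEX15 each lost the call when 1 library was left out.

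To assess what eIF2A depletion changes in embryonic stem cells, eIF2A shRNA was compared with control shRNA in H9. By camera at its preset correlation, transcripts for cytosolic ribosomal proteins, the respiratory chain, glycolysis and ATF4 target genes fell, and p53 target transcripts rose; for these lists adjusted p = 0.18 to 0.21 with an estimated correlation. A possible sign of RNA or library quality also followed the groups. Reads assigned to no counted feature made up 20.84 and 20.63% with shRNA against 18.84 and 18.39% in the controls. Of 19 histone genes, 7 fell and none rose (median -0.45, and 0.06 with the trend described next removed). This list did not pass camera (adjusted p = 0.33). Its median was close to that of all transcripts under 1000 nt (-0.47), so it is no sign of quality apart from that trend. The list changes were not separated from such a difference, except as far as removing that trend does so. Of 10380 genes called, 5389 rose and 4991 fell, and 2441 changed at least 2-fold (2310 higher, 131 lower). Which direction prevailed depended on scaling: with DESeq2's size factors 4553 rose and 6124 fell (1688 and 271 at least 2-fold), and with upper-quartile scaling 5807 rose and 4452 fell (2551 and 95). The change followed the makeup of the transcripts: the log2 fold change had a Spearman rho of -0.68 with GC content and 0.45 with transcript length across 14489 genes, which are not independent replicates. Its median was 0.85 for transcripts under 45% GC and -0.40 for those over 60%, and -0.47 for transcripts under 1000 nt and 0.55 for those over 4000 nt. In HEK293T both rho values were -0.10, and between replicates of a group they were at most 0.17 in size. With this trend removed, 7227 genes were called in H9 (3434 higher, 3793 lower) and 594 changed at least 2-fold (343 higher, 251 lower). Of 89 genes called in H9 and taken for naming, 59 had a change smaller by more than 1.5 times in that fit, 5 turned direction and 12 were not called, so the sizes below, which are as measured, depend on it.

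**Figure D2:**
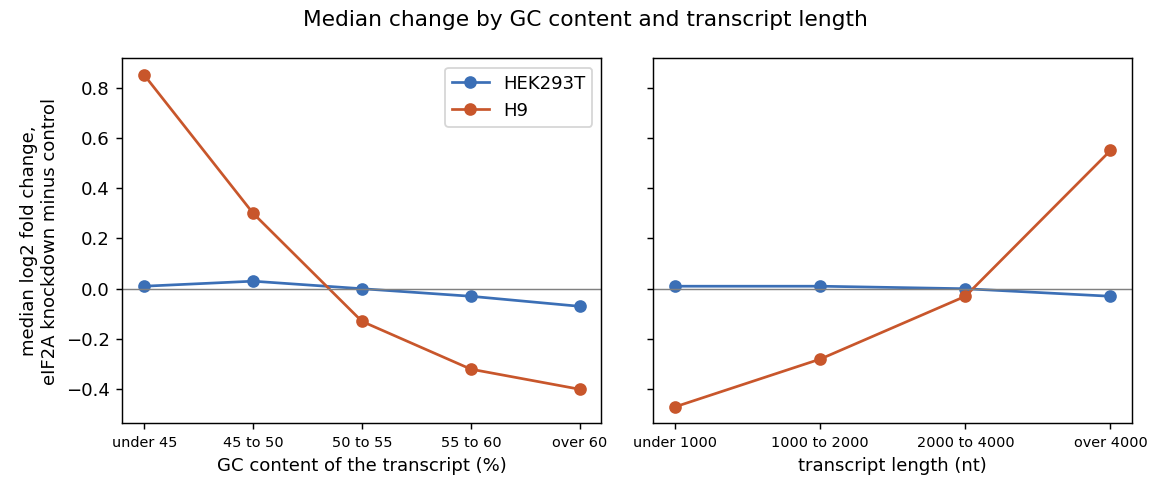
Median log2 fold change (eIF2A knockdown minus control) of genes grouped by the GC content (percent) and length (nt) of their transcripts, for HEK293T in blue and H9 in orange. The H9 medians run from 0.85 to -0.40 with rising GC content and from -0.47 to 0.55 with rising length, while the HEK293T medians stay between -0.07 and 0.03.

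Of 75 cytosolic ribosomal protein genes, 72 fell in H9 and none rose, with a median of -0.58 (camera adjusted p = 4.8e-21; adjusted p = 0.21 with an estimated correlation). RPS16 fell by 0.72 ± 0.029, RPL13 by 0.67 ± 0.029, RPL18 by 0.66 ± 0.028 and RPS28 by 0.74 ± 0.032. With the GC and length trend removed 53 of the list fell and 5 rose (median -0.25, camera adjusted p = 7.3e-15), and RPS16 (-0.06) and RPL18 (-0.02) were no longer called. Of 33 nuclear-encoded respiratory chain subunits, 27 fell and 4 rose, with a median of -0.46 (camera adjusted p = 1.2e-06; adjusted p = 0.18 with an estimated correlation; trend removed, median -0.21 and adjusted p = 9.2e-06). UQCRC1 and COX7C, subunits of complexes of that chain, fell by 0.62 ± 0.031 and 0.62 ± 0.032. Of 24 glycolysis and hypoxia genes, 15 fell and 5 rose (median -0.32, camera adjusted p = 0.023; adjusted p = 0.18 with an estimated correlation; trend removed, median -0.12 and adjusted p = 0.034). Aldolase ALDOA fell by 0.58 ± 0.028 and enolase ENO1 by 0.53 ± 0.027, and the glucose transporter SLC2A3 rose by 0.60 ± 0.031.

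In the integrated stress response list, 19 of 30 genes fell in H9 and 7 rose, with a median of -0.35 (camera adjusted p = 0.0075; adjusted p = 0.18 with an estimated correlation; trend removed, median -0.21 and adjusted p = 0.0031). The mitochondrial enzymes PCK2 (-0.99 ± 0.034), SHMT2 (-0.85 ± 0.030), ALDH18A1 (-0.81 ± 0.033) and PYCR1 (-0.80 ± 0.033) fell, and ATF4 itself fell by 0.63 ± 0.031. Of 20 p53 targets, 15 rose and 3 fell, with a median of 0.91 (camera adjusted p = 0.0023; adjusted p = 0.18 with an estimated correlation). MDM2 rose from 12.1 to 38.5 CPM (log2 fold change 1.66 ± 0.073), the cyclin-dependent kinase inhibitor CDKN1A from 17.1 to 43.2 CPM (1.34 ± 0.072), CCNG1 by 1.04 ± 0.048 and the death receptor TNFRSF10B by 0.78 ± 0.044. With the trend removed, 15 of the list rose and none fell, with a median of 0.58. Of 24 mitosis genes, 16 rose and 5 fell (median 0.55, camera adjusted p = 0.025; adjusted p = 0.18 with an estimated correlation). KIF23 rose by 1.57 ± 0.080, the proliferation marker MKI67 by 1.49 ± 0.075 and the kinase BUB1 by 1.13 ± 0.058, and UBE2C fell by 0.73 ± 0.033. The mitosis list did not pass with the trend removed (median 0.05, adjusted p = 0.35) or with DESeq2's size factors (adjusted p = 0.059). Adjusted over the list alone, 73 ribosomal protein genes, 27 respiratory chain, 15 glycolysis, 19 stress response, 3 p53 and 5 mitosis genes fell, and 0, 4, 5, 7, 15 and 16 rose. With the trend removed, the smallest adjusted p of any list with an estimated correlation was 0.060 in H9 and 0.054 in HEK293T.

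Among pluripotency genes in H9, 16 of 28 rose and 8 fell (camera adjusted p = 0.060), with the deubiquitinase USP44 at 1.27 ± 0.056 and L1TD1 at 1.01 ± 0.045. The core factor SOX2 rose by 0.47 ± 0.049. POU5F1 had a log2 fold change of -0.48 ± 0.14 (adjusted p = 0.027), and this call was lost when only the 4 H9 libraries were fitted (adjusted p = 0.13). NANOG had one of -0.07 ± 0.056 (adjusted p = 0.29), and of -0.78 with the trend removed. Markers of other cell types went both ways: 4 of 15 neural markers rose and 4 fell, with TUBB3 at -1.10 ± 0.035 and NES at 1.03 ± 0.036. Of mesoderm and endoderm markers 3 of 16 rose and 1 fell, with KDR at 1.2 ± 0.067. Of trophoblast markers 4 of 12 rose and 2 fell, and of fibroblast markers 3 of 11 rose and 4 fell, with THY1 at -0.42 ± 0.033 and COL1A1 at 0.46 ± 0.043.

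Of 53 cap-binding and initiation factors, 27 rose and 22 fell in H9, with the import receptor KPNB1 at 1.08 ± 0.035 and EIF4G2 at 0.94 ± 0.031. NCBP1 rose by 0.92 ± 0.062, NCBP2 by 0.56 ± 0.059, EIF2S1 by 0.70 ± 0.056 and EIF4E by 0.35 ± 0.064. With the trend removed these values were 0.01, 0.90, -0.21 and -0.80, and DESeq2 did not call EIF4E (adjusted p = 0.059). In the unfolded protein response list 11 of 20 genes rose and 5 fell (camera adjusted p = 0.057; trend removed, camera adjusted p = 0.0061 and adjusted p = 0.22 with an estimated correlation), with CANX at 1.22 ± 0.035 and HSP90B1 at 1.47 ± 0.042. In the heat shock list 10 of 23 rose and 10 fell, with HSP90AA1 at 1.24 ± 0.038 and HSPD1 at 0.92 ± 0.034. Of aminoacyl-tRNA synthetases, 10 of 19 rose and 9 fell, with IARS1 at 1.03 ± 0.040. Of NRF2 genes, 6 of 24 rose and 11 fell, with PRDX1 at -0.54 ± 0.030. Of immediate early genes, 6 of 20 rose and 8 fell, with JUN at 1.25 ± 0.055 (8 and 3 with the trend removed), and of interferon genes 5 of 16 rose and 3 fell. Cholesterol genes gave 9 of 22 higher and 13 lower (MVD -0.87 ± 0.042), and the list had a camera adjusted p of 0.40 as measured and of 0.019 with the trend removed (median -0.16; adjusted p = 0.17 with an estimated correlation). DNA replication genes gave 9 of 24 higher and 9 lower, and nonsense-mediated decay factors 6 of 16 higher and 6 lower (SMG1 1.80 ± 0.094). Known substrates of that decay gave 6 of 15 higher and 8 lower, and metallothioneins 1 of 8 higher and 2 lower. Histones, listed as a possible sign of RNA quality, gave 0 of 19 higher and 7 lower. Metallothioneins gave, with the trend removed, 4 higher and 0 lower (median 0.51, against -0.07 as measured), histones 1 higher and 2 lower (0.06, against -0.45), the cap-binding and initiation factors 18 higher and 23 lower, and the DNA replication genes 11 higher and 6 lower; none of these lists passed camera in either fit. Among genes with a mean of at least 1 CPM, the largest rises were in KITLG (3.03 ± 0.37, from 0.262 to 2.17 CPM), RORA, CAVIN4, FAM171B, ANK3, the cholesterol exporter ABCA1 (2.29 ± 0.12, from 3.86 to 19.0 CPM), TMOD2, ALCAM, USP53 and THSD7A. The largest falls in that range apart from EIF2A were in IL17C (-2.27 ± 0.37), GALNT9, MYL4, SAC3D1, STOML3, FBP1, CD79B, PECR and the small GTPase ARF5 (-1.56 ± 0.035, from 369 to 125 CPM).

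**Figure D3:**
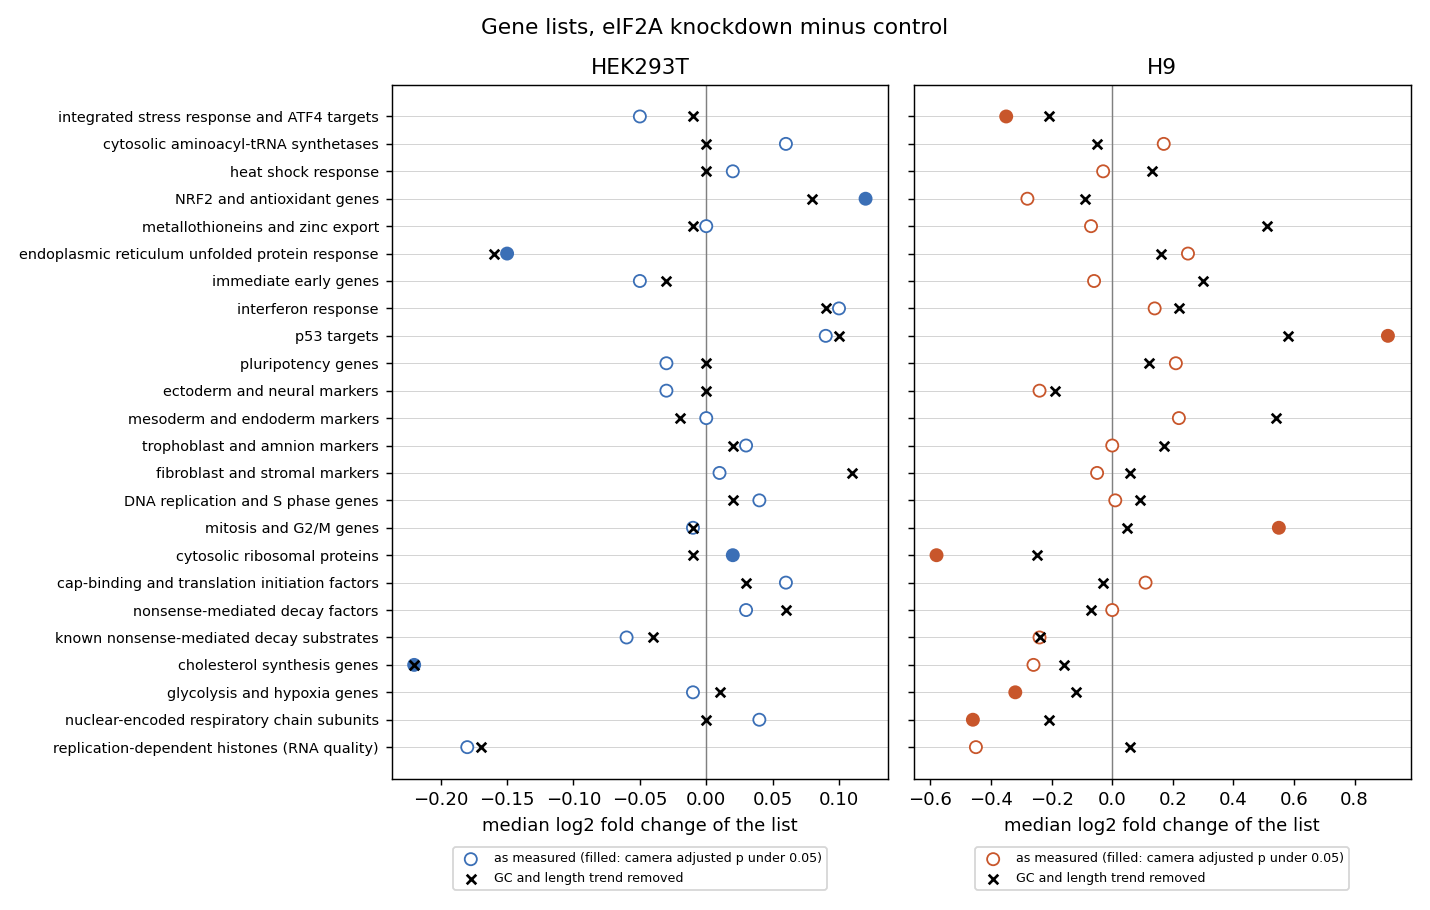
Median log2 fold change (eIF2A knockdown minus control) of the members of each of the 24 gene lists in HEK293T and in H9; circles are the medians as measured, filled where the camera adjusted p was under 0.05, and crosses are the medians with the GC and length trend removed; the panels differ in the range of their axes. In H9 the p53 targets lie at 0.91 as measured and at 0.58 with the trend removed, and the ribosomal proteins at -0.58 and -0.25.

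The difference between the comparisons was tested next. The experiments also differ in arsenite, given only to HEK293T, and in siRNA against shRNA, so it is the difference between the experiments as done. The change differed for 8467 genes (4532 higher in H9, 3935 lower), and for 6198 with the GC and length trend removed. HSP90B1, JUN and MDM2 fell in HEK293T and rose in H9, with log2 differences of 1.79, 1.57 and 2.20 (1.22, 1.74 and 1.08 with the trend removed). Of the lists, 7 differed by camera: ribosomal proteins (median difference -0.60), respiratory chain subunits (-0.47), stress response (-0.34), NRF2 (-0.26) and glycolysis genes (-0.26) were lower in H9 relative to HEK293T, and p53 targets (0.88) and the unfolded protein response (0.37) were higher. These medians were, with the trend removed, -0.32, -0.23, -0.21, -0.13, -0.15, 0.46 and 0.30. Adjusted p with an estimated correlation was 0.13 to 0.28 for these lists, and the NRF2 and glycolysis differences did not pass with the trend removed (adjusted p = 0.085 and 0.082). The NRF2 difference was -0.15 without HEK293T arsenite eIF2A siRNA replicate 1, and with DESeq2's size factors the NRF2, unfolded protein response and glycolysis differences were -0.42, 0.21 and -0.41, against -0.18, 0.45 and -0.17 with upper-quartile scaling. The largest differences named here were in GRHL2, RGCC, MECOM, SOX18 and DNER (higher) and KLK10, PCDHGA10 and SIT1 (lower). Each of these had at most 5 counts per library in one of the lines, so no fold is given, and with the trend removed MECOM (adjusted p = 0.13), DNER (0.056) and SIT1 (0.095) did not differ.

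To assess whether the same genes changed in both lines, the calls were overlapped. As measured, 1273 genes fell in both against 731 for independent lists (odds ratio 3.46, Fisher's exact test, adjusted p = 8.2e-149 over 4 tests). The test treats genes as independent replicates, which they are not, so its p-values overstate the evidence and the counts are a description. Rises shared 756 genes against 758 (odds ratio 1, adjusted p = 0.94). A further 846 genes rose in HEK293T and fell in H9 against 702 (odds ratio 1.42), and 465 fell in HEK293T and rose in H9 against 790 (odds ratio 0.42). Across genes, the log2 fold changes had a Pearson r of -0.034 and a Spearman rho of -0.001. With the GC and length trend removed, 614 genes fell in both against 479 (odds ratio 1.51), 430 rose in both against 510 (0.78), 933 rose in HEK293T and fell in H9 against 563 (2.54), and 470 fell in HEK293T and rose in H9 against 433 (1.13, adjusted p = 0.032), so the deficit of that last group was not kept. After EIF2A, the largest changes in the same direction were in ZNF700, ZNF160, ABCA5 (higher) and the muscarinic receptor CHRM1 (-1.81 ± 0.45 in HEK293T, -1.22 ± 0.33 in H9). BRCA2, PREX2 and KDR fell in HEK293T and rose in H9, and CEND1 and FBP1 did the opposite. In HEK293T these genes other than BRCA2 had at most 40 counts per library, and ZNF700, ZNF160, ABCA5, CEND1, PREX2, FBP1 and KDR lost the call there when 1 library was left out; in H9, BRCA2 (0.19, adjusted p = 0.43) and ABCA5 (0.96, adjusted p = 0.18) were not called with the trend removed, nor was ABCA5 without H9 control shRNA replicate 2 (adjusted p = 0.074).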

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

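The tests with the GC and length trend removed and the leave-one-out readings below were chosen after the results had been seen. Results given for both lines were listed where a test of the difference itself, H9 minus HEK293T, passed; the lines also differ in arsenite and in siRNA against shRNA. The change differed for 8467 genes. Median log2 differences were -0.60 for ribosomal proteins, -0.47 for respiratory chain subunits, -0.34 for stress response genes, -0.26 for NRF2 genes, -0.26 for glycolysis genes, 0.37 for the unfolded protein response and 0.88 for p53 targets, by camera at its preset correlation; with the trend removed they were -0.32, -0.23, -0.21, -0.13, -0.15, 0.30 and 0.46. For these lists adjusted p = 0.13 to 0.28 with an estimated correlation, and NRF2 and glycolysis genes did not pass with the trend removed (adjusted p = 0.085 and 0.082). Of 21 genes given for both lines, 15 differed. Log2 differences were 2.91 for KDR, 2.91 for PREX2, 2.64 for BRCA2, 2.20 for MDM2, 1.79 for HSP90B1, 1.57 for JUN, 0.92 for CDKN1A, 0.71 for NCBP1, 0.53 for EIF2S1, 0.48 for NCBP2, -0.48 for MVD, -0.51 for SHMT2, -0.59 for ATF4, -2.80 for FBP1 and -2.87 for CEND1. The count of 15 was partly fixed by how genes were chosen. KDR, PREX2, BRCA2, FBP1 and CEND1 were taken as called in opposite directions, so their large differences are no separate support. ZNF700, ZNF160, ABCA5 and CHRM1, which did not differ, were taken as called in the same direction. In HEK293T, KDR had only 10 and 9 counts in the controls, against 6 and 0 with siRNA. In the fit with the trend removed, NCBP1 (-0.19, adjusted p = 0.095) and MVD (-0.07, adjusted p = 0.37) did not differ, EIF2S1 turned to -0.37, and the differences of KDR, PREX2, BRCA2, MDM2, HSP90B1, JUN, CDKN1A, NCBP2, SHMT2, ATF4, FBP1 and CEND1 were 2.33, 1.71, 1.40, 1.08, 1.22, 1.74, 1.27, 0.87, -0.16, -0.23, -2.36 and -2.43. EIF4E differed in that fit (-1.03) and not as measured (adjusted p = 0.096). EIF2A did not differ as measured (adjusted p = 0.94) and did with the trend removed (adjusted p = 8.4e-04). For the genes near 0 counts in one line, the adjusted p of the difference was 0.0062 for GRHL2, 0.040 for RGCC, 0.042 for MECOM, 0.039 for SOX18, 0.041 for DNER, 0.0047 for KLK10, 0.0044 for PCDHGA10 and 0.042 for SIT1; with the trend removed MECOM (0.13), DNER (0.056) and SIT1 (0.095) did not differ. In counters outside the gene counts, reads assigned to no counted feature made up 2.12 percentage points more in the H9 eIF2A libraries (20.84 and 20.63%) than in the H9 controls (18.84 and 18.39%). In HEK293T they made up less with siRNA (14.98 and 14.95%) than in the controls (15.59 and 17.68%).

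The H9 changes followed GC content and transcript length. With the fitted trend removed, 7227 genes were called, and 4975 of the 10380 called genes kept their call and direction. The fitted trend was thus not the whole of the calls. The fit removes only a smooth trend with properties of the longest matching transcript, and the number that unrelated calls would share was not computed. A bias of the libraries as the whole cause therefore stays open. It also stays open for the rises of at least 2-fold, whose number went from 2310 to 343. The trend follows the groups (rho with GC content of -0.68, against at most 0.17 between replicates). A bias of RNA or library preparation and an effect of the knockdown on GC-poor, long transcripts thus cannot be told apart. The fit removes either one.

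The rise of p53 targets in H9 was tested against the same trend. With it removed, the list's median went from 0.91 to 0.58 and its camera adjusted p was 1.1e-08 (adjusted p = 0.060 with an estimated correlation), which argues against the trend as the whole cause. No H9 library decided the rise: with each left out the median was 0.88 to 0.93 and the largest adjusted p was 0.0067. A response to the loss of eIF2A may account for it and stays a hypothesis. Delivery of the shRNA and its effects on other targets were not tested. As measured, the list passed camera at the preset correlation of 0.01 and not with the correlation estimated. The estimate for this list was -0.024, below the preset, so a higher correlation between its genes was not what ended the call.

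The fall of cholesterol synthesis genes in HEK293T was tested likewise. With the trend removed the list's median was -0.22 and its camera adjusted p 6.0e-09 (adjusted p = 0.054 with an estimated correlation). HEK293T had little of this trend: both rho values were -0.10, and the medians by GC content and length lay between -0.07 and 0.03. The trend was thus too small to be the whole cause, and its removal could change little and adds no support. The HEK293T controls differed from each other more than other replicates, yet with each HEK293T library left out the median was -0.25 to -0.22 and the largest adjusted p was 2.2e-06. An effect of eIF2A depletion under arsenite may account for the fall and stays a hypothesis; effects of the siRNA on other targets were not tested.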

How the results depend on the processing

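The fit with the GC and length trend removed, and upper-quartile scaling of lists and genes, were chosen after the data had been seen. The EIF2A fall kept its direction and call under all alternatives run, but with the trend removed it differed between the lines (-1.685 in HEK293T, -2.305 in H9, adjusted p = 8.4e-04), and the counts of called genes in H9 and of differing genes stayed within 1.5 times. In HEK293T, DESeq2 called 2742 genes (22 at least 2-fold) and gave no adjusted p to 3389 of 14565; the count of at least 2-fold was 32 with the stricter filter and 41 at an adjusted p under 0.01. With the trend removed, 594 genes in H9 changed at least 2-fold, 1044 calls were shared in the same direction (2029 without the correction), and 2 lists passed in HEK293T. With an estimated correlation 0 lists passed in HEK293T, 0 in H9 and 0 for the difference, and with fry 7, 19 and 16 passed; fry does not compare a list with other genes. The estimate lay below the preset of 0.01 in H9 for p53 targets (-0.024), mitosis (-0.028), glycolysis (-0.027) and stress response genes (0.007). In HEK293T it did so for cholesterol (-0.033) and NRF2 genes (-0.024). A higher correlation was thus not what ended these calls. The estimate was above the preset for ribosomal proteins (0.318 in H9, 0.311 in HEK293T), the H9 respiratory chain (0.024) and the HEK293T unfolded protein response (0.137). Other causes were not tested. Scaling moved the centre in H9: the median log2 fold change of all genes was 0.024 with TMM, -0.126 with DESeq2's size factors and 0.095 with upper-quartile scaling, so H9 directions are relative to that. The share of H9 calls that were higher was 51.9% with TMM, 42.6% with those factors, 41.9% with DESeq2 and 56.6% with upper-quartile scaling, and for the difference 53.5%, 42.5%, 41.0% and 60.2%.

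Labels do not say what a set is, and the deviations of equal-numbered libraries correlated at -0.015 in HEK293T and 0.005 in H9. No shared signature of a set was thus seen, but these correlations cannot tell whether libraries of a set were grown or prepared together. With the set as a replicate block, 3847 genes were called in HEK293T, 10281 in H9 and 8327 for the difference. When only the 4 libraries of a line were fitted, 3679 of 13294 genes were called in HEK293T and 10581 of 13828 in H9. Of the named genes' values, 176 of 179 kept direction and call with the block and 158 with the trend removed, where SLC30A1 (-0.073), MT1X (0.101), H1-2 (0.062), EIF4E (-0.801) and EIF2S1 (-0.208) turned sign in H9. NANOG in H9 stood at 0.003 with upper-quartile scaling, and ATF4 in HEK293T ranged from -0.074 to 0.005 with 1 library left out, turning sign without HEK293T arsenite control siRNA replicate 2; neither turned value was called. DESeq2 gave no adjusted p for 19 of the values. At these depths and 2 libraries per group, simulated changes of 0.5 on the log2 scale were recovered in 65.1% of cases for H9 and 70.2% for HEK293T; depth was not varied. With any 1 library left out, the called genes numbered 2903 to 4079 in HEK293T, 9522 to 10597 in H9 and 7818 to 8496 for the difference.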

Other observations

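Gene families picked by symbol after the data had been seen add to the lists. Adjusted p-values in this section were taken over these 4 families within a comparison and fit, not over the 24 lists. They are therefore adjusted less strictly than those of the lists and cannot be set against them. In H9, 59 of 76 mitochondrial ribosomal protein genes fell and 7 rose with eIF2A shRNA (median log2 fold change -0.37, camera adjusted p = 8.1e-09; adjusted p = 0.16 with an estimated correlation), and 41 fell and 8 rose with the GC and length trend removed (median -0.12, adjusted p = 4.0e-06; 0.033 with an estimated correlation). Of 36 proteasome subunit genes, 21 fell and 12 rose in H9 (median -0.28, camera adjusted p = 0.012; adjusted p = 0.26 with an estimated correlation), and 17 fell and 7 rose with the trend removed (median -0.10, camera adjusted p = 0.0041; adjusted p = 0.047 with an estimated correlation). In HEK293T, 19 proteasome genes rose and 1 fell with eIF2A siRNA (median 0.10, camera adjusted p = 6.9e-06; adjusted p = 0.089 with an estimated correlation), and 14 rose and 2 fell with the trend removed (median 0.06, camera adjusted p = 0.0070; adjusted p = 0.14 with an estimated correlation). Of the mitochondrial ribosomal protein genes, 24 rose and 7 fell in HEK293T (median 0.06, camera adjusted p = 4.5e-04; adjusted p = 0.27 with an estimated correlation), which did not pass with the trend removed (adjusted p = 0.12). Of 8 chaperonin subunit genes, 5 rose in HEK293T (median 0.15, camera adjusted p = 4.5e-04; adjusted p = 0.089 with an estimated correlation, and 0.054 with the trend removed), and 5 rose and 3 fell in H9 (median 0.30, camera adjusted p = 0.21), where 1 rose and 4 fell with the trend removed (median -0.09, adjusted p = 0.13).

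Of 456 zinc finger genes with ZNF symbols, whose transcripts had a median GC content of 43.8%, 273 rose and 73 fell in H9 (median 0.68, camera adjusted p = 0.0018; adjusted p = 0.081 with an estimated correlation). In HEK293T, 27 rose and 46 fell (camera adjusted p = 0.41). The hypothesis that the GC and length trend is the whole cause of the H9 rise was tested by removing it. With it removed, 124 genes rose and 63 fell and the median went to 0.15 (camera adjusted p = 0.015; adjusted p = 0.047 with an estimated correlation). Most of the rise went with the trend, and a small part may be separate from it. That part rests on a family chosen after the data had been seen and on adjustment over few families.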
